A study of Danio rerio with 2 samples.

How the data were processed

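Cells dissociated from zebrafish (Danio rerio) thyroid glands had been profiled with 10x Genomics droplet RNA sequencing. One library came from fish of 2 mpf and one from fish of 8 mpf, where mpf is the usual abbreviation of months post fertilisation. Both ages were of a transgenic line in which the thyroglobulin promoter drives the fluorescent protein mVenus and the enzyme NTR, per the labels. The series' text names Cell Ranger 2.1.0 for alignment and counting, with an expected number of 6000 cells, the GRCz10 genome and the Ensembl 87 annotation limited to protein-coding, lincRNA and antisense genes. The number of fish per library and any sort of the cells are not given in the sources used here. Whether the barcode lists were filtered after Cell Ranger is not given in the sources used here either.

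The deposited tables hold whole-number UMI counts per gene symbol and cell barcode, with no normalization by the authors. Each table has 27374 gene rows. The 2 mpf table holds 6940 barcodes and 24025180 UMIs, with 500 UMIs in its shallowest barcode. The 8 mpf table holds 6166 barcodes and 22838925 UMIs, with 356 UMIs in its shallowest barcode, so the 2 tables had not been limited to one minimum depth. No cell annotation came with the tables. No ERCC spike-in UMI was present in either table.

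Choices made before the data were examined were the filters, the clustering settings, the marker and gene lists, the rule for naming genes, and all alternatives except those said below to be later. Barcodes were kept with at least 500 UMIs, at least 200 detected genes and at most 25% of UMIs from mt- genes. At 2 mpf these filters removed 0, 77 and 176 barcodes, and at 8 mpf 433, 143 and 226, where a barcode can miss more than 1 filter. Scrublet, as implemented in scanpy, was run per library with an expected doublet rate of 6%. Its own threshold marked 0% and 0.0360% of barcodes, so it had not worked. As fixed for that case, barcodes were removed above a score set by the top 6% of scores, which took out 395 barcodes (5.88%) at 2 mpf and 303 (5.46%) at 8 mpf. This left 6328 cells at 2 mpf with a median of 1768 UMIs, and 5250 cells at 8 mpf with a median of 3054 UMIs.

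Counts of both libraries were scaled to 10000 per cell and log-transformed for clustering only. Clustering used 2000 highly variable genes chosen within each library, 30 principal components, 15 nearest neighbours and the Leiden algorithm at resolution 1, without batch integration, and gave 29 clusters. Markers of 23 cell classes had been fixed, and 252 of 271 marker entries matched a gene row. The scoring thresholds were set after seeing the data. A marker counted as found in a cluster if its CPM (UMI counts scaled by the total of the cells summed), with an offset of 10 CPM, was at least 4 times the median over clusters and at least 10% of the cluster's cells had a UMI. A cluster took the class with the largest share of its markers found. It needed at least 3 found markers, a lead of 10 percentage points over the next class, and no other class with more markers among its top 10 genes by fold. Of the 29 clusters, 22 were named and 7 stayed unnamed. Names are rebuilt from markers, so "thyrocyte-like" and the like are meant throughout where a class is named.

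With 1 library per age, no test between ages was possible, and no p-value, standard error or count of changed genes is given. UMIs were summed over the cells of a class in a library and divided by all UMIs of that class to give CPM. Ratios of CPM at 8 mpf to 2 mpf carry exact conditional binomial 95% intervals, CPM values exact Poisson 95% intervals, and shares of cells exact Clopper-Pearson 95% intervals. All of these cover counting error only, not variation in expression between cells or differences between fish, dissections or libraries. Where a gene had 0 UMIs at one age, a bound was computed against 3 counts over that class in that library, and for a share of 0 the limit given is 3 counts over the number of cells. A class was compared between ages if it had at least 50 cells in each library, which 8 classes had.

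Before the data were examined, 24 gene lists were fixed, with 619 of 664 entries matched, 7 of the marker and list symbols only without regard to case (IYD and DUOXA2, for example, are written so in the tables). They cover thyroid transcription factors, thyroid hormone synthesis and release, thyroid hormone response, AP-1 and immediate early genes, heat shock and dissociation stress, endoplasmic reticulum (ER) chaperones, lysosome and cathepsins, antioxidants and selenoproteins, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, cell cycle, extracellular matrix and collagens, interferon response, antigen presentation, inflammatory and acute phase genes, epithelial junction and cytoskeleton, lipid and cholesterol metabolism, haemoglobins, other red blood cell genes, striated muscle, neuropeptides, growth factor ligands and growth factor receptors. Another 4 lists, for fasting and glucocorticoid response, autophagy, ribosome biogenesis and the circadian clock, were chosen after seeing the data and enter the closing section only. Members with at least 20 UMIs over both libraries in the class were measured, and a list needed 3 of them. A list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean expression. A member with 0 UMIs at one age entered at its bound. Where a list median is called centred or relative to all genes, the median of all measured genes of the class was subtracted. Counts of members at least 2-fold higher or lower, and ratios of single genes, were not centred in this way. A percentile describes these 2 libraries only. Random lists could hold members of the other lists. Because they are matched on expression, a list near the median of all genes can still lie low or high among them.

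Genes were named by a rule fixed in advance. For thyrocytes, these were the 12 highest and the 12 lowest by the bound of the ratio's interval nearest to 1, among genes with at least 50 UMIs whose CPM in the class, in the library where it was higher, was at least 50% of that in all other kept cells of that library. The other classes had 5 each way by the same rule. Members of lists were named by UMIs or ratio, up to 4 per list. A set of 14 thyroid and AP-1 genes was to be named where measured. Of these, hhex was not analysed here because its symbol matched no row, and 1 other is not used here as a single gene. Thyrocytes were compared with the other classes within each library, and a gene was called higher only if so in both libraries without overlap of the intervals. For this, named classes of at least 50 cells in the library were used, a limit set after seeing the data. Variation between thyrocytes was measured after thinning each cell to 1 fixed number of UMIs. A depth of 1500 UMIs was planned, but only 71.0% and 55.8% of thyrocytes reached it, and the fallback fixed in advance, 1100 UMIs, was used.

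Alternatives fixed in advance changed the minimum UMIs, the mitochondrial limit, doublet removal, the clustering resolution, the number of variable genes, joint clustering, the scaling, the summing over cells, the depth of each cell, the gene minimums and the thinning depth. Splitting thyrocyte barcodes at 5000 UMIs, and regrouping the fibroblast clusters, were added after seeing the data. The intervals were tested on simulated data for 4262 genes, with means and totals taken from tg-rich barcodes. Of the 95% intervals, 95.8% held the true ratio. Summed counts were drawn with counting error only, as the intervals assume, so this checks the computation and not the effect of variation between cells. Of the genes simulated 2-fold higher and 4-fold lower, 92% and 94% had an interval wholly on the simulated side of 1. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9. Gene symbols are those in the tables. Genomic positions were not analysed here.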

Results

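The data are UMI counts per gene and cell barcode for dissociated zebrafish thyroid glands, with 1 library at 2 mpf and 1 at 8 mpf. The 2 mpf library held 24025180 UMIs in 6940 barcodes, with a median of 1814.5 UMIs per barcode. The 8 mpf library held 22838925 UMIs in 6166 barcodes, with a median of 2764.5. After filtering, 6328 cells with 21674231 UMIs remained at 2 mpf, and 5250 cells with 20799479 UMIs at 8 mpf. The median number of detected genes per kept cell was 749 at 2 mpf and 875 at 8 mpf. There were no replicates at either age, so a difference between the ages below is a difference between these 2 libraries. All intervals are 95% intervals for counting error only. Genes are given by the symbols in the tables, which carry no gene identifiers or positions, and expression is given in CPM, the UMIs of a gene scaled by all UMIs of the cells summed.

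The first comparison asks which cell types the gland tissue yielded at each age. Thyrocyte-like cells, the hormone-producing cells recognised by genes such as tg, made up 321 of 6328 cells at 2 mpf (5.07%, interval 4.54 to 5.64) and 163 of 5250 at 8 mpf (3.10%, 2.65 to 3.61). Epithelial-like cells were 8.68% (7.99 to 9.40) of cells at 2 mpf and 17.0% (16.0 to 18.0) at 8 mpf, a 1.96-fold higher share. Neutrophil-like cells were 0.601% (0.425 to 0.823) and 2.48% (2.07 to 2.93), a 4.12-fold higher share at 8 mpf. Mural-like cells, the contractile cells around vessels, were 5.33% (4.79 to 5.91) at 2 mpf and 0.476% (0.308 to 0.702) at 8 mpf, an 11.2-fold lower share. An unnamed cluster with acta2 and tagln among its top 10 genes is not counted in that share. It had 6 mural and 9 fibroblast markers found, and held 3.16% and 0.990% of cells, so the fold depends on the naming. Endothelial-like cells were 3.59% (3.14 to 4.08) and 1.05% (0.790 to 1.36), a 3.42-fold lower share at 8 mpf.

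Macrophage-like cells made up 5.93% (5.36 to 6.54) of cells at 2 mpf and 9.45% (8.67 to 10.3) at 8 mpf. Over the alternatives their share ran from 3.83% to 6.13% at 2 mpf and from 7.97% to 13.1% at 8 mpf. T-cell-like cells were 2.97% (2.57 to 3.42) and 4.44% (3.90 to 5.03). Their clusters of 311 and 110 cells each had 6 of 12 markers found, such as runx3 and ccr9a but not lck, zap70, cd4-1 or cd8a. The larger cluster also had 6 macrophage markers found, and the smaller had il4 and il13 among its top 10 genes. The T cell name is therefore uncertain. Lymphatic endothelial-like cells were 1.82% (1.503 to 2.18) and 2.65% (2.23 to 3.12). Proliferating cells were 1.01% (0.780 to 1.29) and 1.05% (0.790 to 1.36), with overlapping intervals. Thrombocyte-like cells were 27 at 2 mpf (0.427%) and 3 at 8 mpf (0.0571%). A neural or neuroendocrine class with tph1a and grp had 28 cells at 8 mpf (0.533%, 0.355 to 0.770) and 0 at 2 mpf, which allows a share of up to 0.0474% at a limit of 3 counts.

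Fibroblast-like cells were the largest class at 2 mpf, with 3246 cells (51.3%, 50.1 to 52.5), and numbered 1018 at 8 mpf (19.4%, 18.3 to 20.5). The class was built from different clusters at each age. Its largest cluster at 2 mpf had 1352 cells there and 112 at 8 mpf, while its largest at 8 mpf had 758 cells there and 719 at 2 mpf. Unnamed clusters held 13.3% of cells (12.5 to 14.2) at 2 mpf and 38.4% (37.0 to 39.7) at 8 mpf. A pair of unnamed clusters with high agrp2 and ccl25b, and with fewer than 3 fibroblast markers found, together held 1.63% and 29.4% of cells. Counted with the fibroblast class, they brought it to 52.9% at 2 mpf and 48.8% at 8 mpf, a grouping chosen after seeing the data. The other unnamed clusters held 3.16% and 0.990%, 5.58% and 2.84%, 1.74% and 4.63%, 0.680% and 0%, and 0.506% and 0.514% of cells at 2 mpf and 8 mpf.

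For thyrocyte-like and fibroblast-like cells the shares are given without a direction, because IYD and the collagens that help define them differed between the libraries. The clustering set several shares: the fibroblast-like share was 24.6% and 51.7% when each library was clustered alone, T-cell-like cells were 0.917% and 0.990% at a resolution of 0.5, no mural-like cluster was named at that resolution, and none was named endothelial-like or mural-like at 8 mpf with separate clustering.

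**Figure D1:**
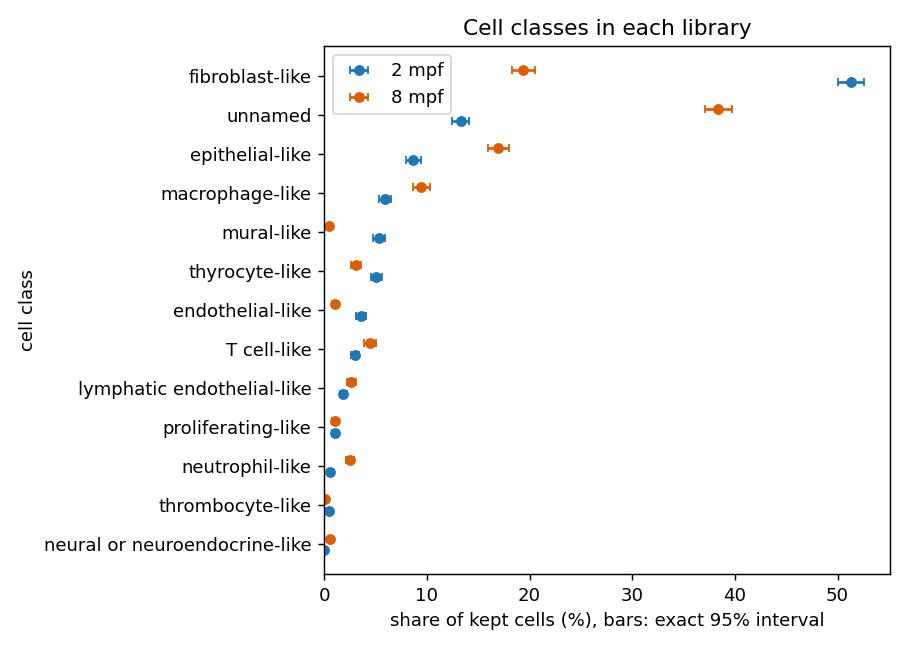
Share of kept cells in each cell class, in percent, for 6328 cells at 2 mpf and 5250 cells at 8 mpf, with bars for exact 95% intervals. Fibroblast-like cells sit at 51.3% and 19.4% and unnamed cells at 13.3% and 38.4%, while thyrocyte-like cells sit at 5.07% and 3.10%.

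The second comparison asks how expression in thyrocyte-like cells at 8 mpf differed from that at 2 mpf. IYD, which recycles iodide from iodotyrosines, was 605 CPM at 2 mpf and 141 CPM at 8 mpf, 4.29-fold lower (3.57 to 5.19). pax8, a transcription factor of thyroid development and function, was 2.26-fold lower at 8 mpf (1.85 to 2.78), at 131 CPM against 296. dio1, a deiodinase that converts thyroid hormones, was 3.46-fold higher (2.91 to 4.12), at 386 CPM against 111. crhbp, which binds corticotropin-releasing hormone, was 11.3-fold higher (9.08 to 14.3), at 542 CPM against 47.8. bgna, which encodes the proteoglycan biglycan, was 7.33-fold higher (5.89 to 9.18), at 399 CPM against 54.4. These rest on 1965590 UMIs from 321 cells with a median of 5909 UMIs, and 899839 UMIs from 163 cells with a median of 2106. The median log2 ratio over the 7358 genes with at least 20 UMIs was −0.29, and list medians are given relative to it. Ratios of single genes and counts of members at least 2-fold higher or lower are not.

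Genes for making thyroid hormone other than IYD differed less. tg, IYD, slc5a5 and tshr also served as markers of the class. tg, which encodes the hormone precursor thyroglobulin, was 31616 CPM at 2 mpf and 26823 CPM at 8 mpf, a ratio of 0.848 (0.836 to 0.861). That log2 ratio of −0.24 was close to the median of all genes and was 0.07 when every cell was thinned to the same depth. slc5a5, the sodium iodide symporter, was 1.34-fold lower at 8 mpf (1.23 to 1.47), at 708 CPM against 950. tshr, the thyrotropin receptor, was 30.5 and 36.7 CPM, with a ratio of 1.201 (0.761 to 1.87). pax2a was 259 CPM at 2 mpf and 134 CPM at 8 mpf, 1.93-fold lower (1.58 to 2.37). Its log2 ratio of −0.95 turned to 0.18 when the CPM of each cell was averaged instead of summing UMIs. nkx2.4b, another thyroid transcription factor, was 341 and 287 CPM, 1.19-fold lower (1.03 to 1.38), and its log2 ratio of −0.25 turned to 0.15 under the same averaging and to 0.20 after thinning. Relative to the median of all genes, the log2 ratio was 0.04 for nkx2.4b and −0.14 for slc5a5. IYD and pax8 were lower and dio1 higher at 8 mpf under every alternative that gave them a value (14 for IYD and pax8, 13 for dio1), with log2 ratios of −2.33 to −1.99, −1.38 to −0.75 and 1.44 to 1.88. Of these alternatives, a higher minimum of UMIs per gene could not change a ratio.

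The genes with the largest differences mostly lay outside the thyroid lists. At 8 mpf, mtss1la had 83 UMIs (92.2 CPM) against 0 at 2 mpf, at least 60.4-fold higher. alpi.1, an intestinal-type alkaline phosphatase, was 42.5-fold higher (24.4 to 80.9), although 46.2% of its 13 UMIs at 2 mpf came from 1 cell. The zinc finger transcription factor genes zbtb16a and zbtb16b were 11.7-fold (6.10 to 24.7) and 7.03-fold higher (4.92 to 10.24), and reads shared between the copies were not analysed here. The glycolytic aldolase gene aldoab was 4.37-fold higher (3.09 to 6.24). The others of the 12 highest were nav2b (9.21-fold), ccser2a (6.71-fold), ivns1abpb (6.36-fold), lmcd1 (6.09-fold) and ankha (5.34-fold). By intervals wholly on 1 side of 1, ivns1abpb was also higher in 7 of 7 other classes measured, zbtb16a in 4 of 6, zbtb16b in 2 of 2 and mtss1la in 2 of 4. In the opposite direction, crhbp was lower in 2 of 2 other classes measured, nav2b in 2 of 3, and alpi.1 and bgna each in 1 of 1.

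Lower at 8 mpf were alcamb, which encodes a cell adhesion molecule, with 330 and 7 UMIs (21.6-fold, 10.4 to 54.1), and pir, a pirin gene, with 294 and 8 UMIs (16.8-fold, 8.43 to 39.3). The cyclin-dependent kinase inhibitor gene cdkn1a had 103 UMIs at 2 mpf and 1 at 8 mpf, 47.2-fold lower (8.28 to 1880), and was lower in 4 of 5 other classes measured. BX511246.1 had 238 and 2 UMIs, 54.5-fold lower (14.9 to 452), and was lower in 6 of 6 other classes measured. With 0 UMIs at 8 mpf, si:dkey-7c18.24 was at least 23.2-fold lower, the fatty acid desaturase gene FADS6 at least 12.4-fold, and birc6-as2 at least 8.70-fold, where strand assignment of this antisense symbol is uncertain. stmn1a, the microtubule regulator stathmin, was at least 11.3-fold lower, with 43.2% of its 74 UMIs at 2 mpf in 1 cell. si:dkey-58i8.5 was 18.6-fold lower (6.22 to 91.5), with 39.3% of its 122 UMIs in 1 cell. zgc:153911 was 8.28-fold lower (6.09 to 11.5). stmn1a and zgc:153911 were each lower in 4 of 5 other classes measured. si:dkey-79f11.10 and si:ch211-183d5.2, at least 8.09-fold and 7.63-fold lower, had all of their UMIs in 1 cell at 2 mpf.

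**Figure D2:**
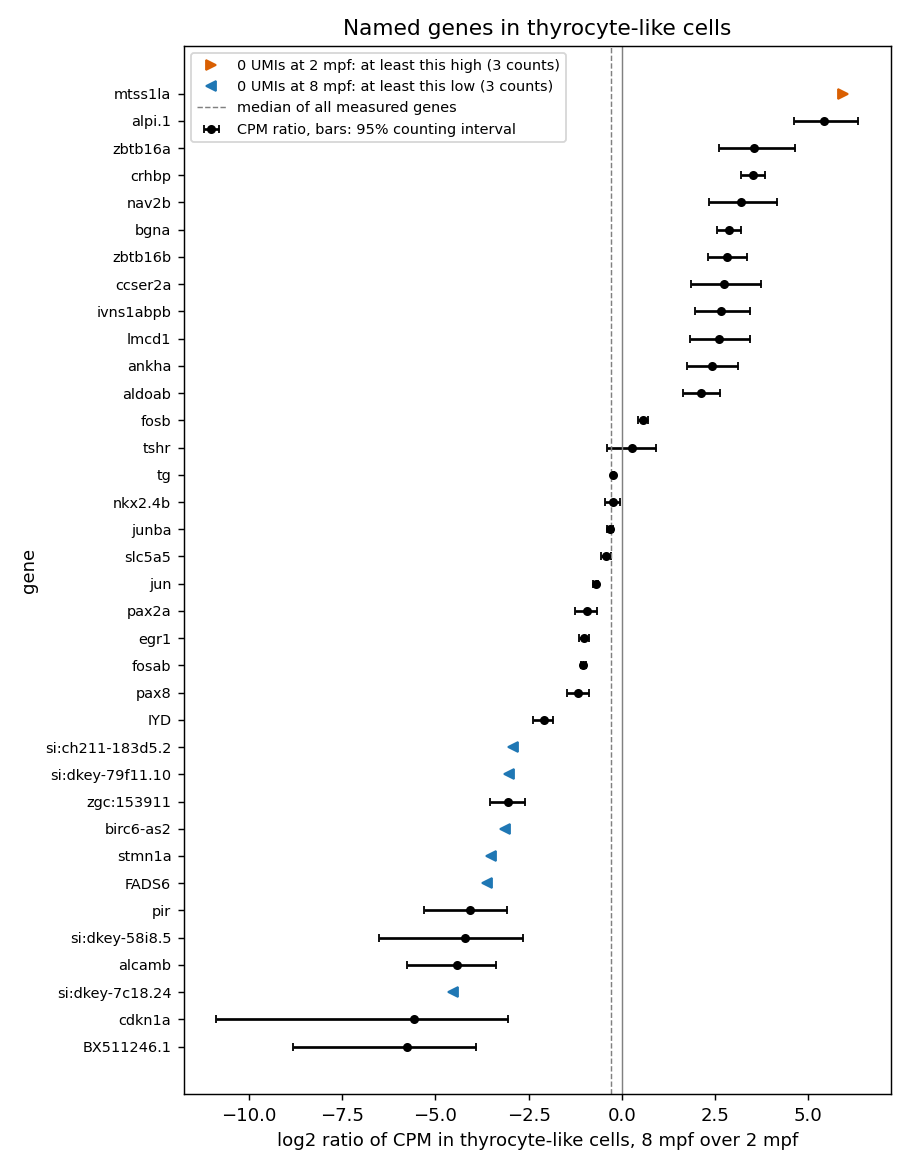
Log2 ratio of CPM in thyrocyte-like cells, 8 mpf over 2 mpf, for the genes named by rule and 12 thyroid and AP-1 genes of a set fixed in advance, with bars for 95% counting intervals and triangles for bounds against 3 counts where 1 age had 0 UMIs. IYD sits at −2.10, pax8 at −1.18 and tg at −0.24, near the dashed median of all genes at −0.29; the signs of tg, pax2a and nkx2.4b turn under other ways of weighting cells.

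Among lists fixed in advance, AP-1 and immediate early genes, which respond within minutes to stimuli including tissue dissociation, were lower at 8 mpf than all matched random lists. Their centred median log2 ratio was −0.37, with 5 of 20 measured members at least 2-fold lower at 8 mpf, 1 at least 2-fold higher and 14 between. The centred median was −0.07 when members with at least 5 UMIs were counted and −0.13 in barcodes of under 5000 UMIs. fosab was 2.06-fold lower (1.97 to 2.16), at 2488 CPM against 5121, egr1 2.01-fold lower (1.83 to 2.22) and nr4a1 4.79-fold lower (2.91 to 8.41). jun was 1.63-fold lower (1.55 to 1.71) and junba was 1625 CPM against 2032, while fosb was 1.48-fold higher (1.35 to 1.63). In barcodes of under 5000 UMIs, a split chosen after seeing the data, the log2 ratio was −0.14 for fosab and −0.37 for egr1, against −1.04 and −1.01 in all thyrocyte-like cells. Heat shock and dissociation stress genes had a centred median of 0.02 (percentile 4.43), with 2 of 17 members at least 2-fold lower. They thus lay near the median of all genes, and low only among genes of like abundance. hspb1, a small heat shock protein gene, was 2.55-fold lower at 8 mpf (2.36 to 2.75). hsp70l had a ratio of 0.890, where reads shared between hsp70 copies were not analysed here. ER chaperone genes had a centred median of −0.10 (percentile 6.09), and −0.42 after thinning, with pdia4 2.59-fold lower and hspa5 1.45-fold lower.

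Cell cycle genes had a centred median of −1.48, below all random lists, with 5 of 10 members at least 2-fold lower at 8 mpf. It was −0.53 when the CPM of each cell was averaged. pcna, a DNA replication clamp, had 145 and 11 UMIs, 6.03-fold lower (3.27 to 12.4), and mcm6 38 and 1 UMIs, 17.4-fold lower (2.94 to 705). Antioxidant and selenoprotein genes had a centred median of −0.27 (percentile 0.130), with 3 of 21 members at least 2-fold lower and 18 within 2-fold. The glutathione transferase gene gstp1 was 2.73-fold lower (2.54 to 2.94), at 943 CPM against 2574, and the peroxiredoxin gene prdx1 was 1.79-fold lower (1.70 to 1.87). Extracellular matrix genes had a centred median of −0.95, below all random lists, with 12 of 22 members at least 2-fold lower, and −1.73 after thinning. col1a2, a type I collagen chain, was 133 and 25.6 CPM, 5.21-fold lower (3.40 to 8.37), beside 3651 and 881 CPM in all other cells. Growth factor ligands had a centred median of −0.50 (percentile 0.255), and from −0.90 to −0.25 over the alternatives, with 9 of 21 members at least 2-fold lower and 1 at least 2-fold higher. Among the lower was pgfb with 58 and 3 UMIs, 8.85-fold lower (2.88 to 44.2). vegfaa, which drives vessel growth, was 1.64-fold lower (1.36 to 1.99).

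Mitochondrially encoded genes had a centred median of 0.75 (percentile 99.95), with all 11 members within 2-fold. It was 0.41 with at most 10% mt- UMIs per cell and 0.45 in barcodes of at least 5000 UMIs, while barcodes under 5000 UMIs, richer in these UMIs, were 46.7% of the class at 2 mpf and 58.3% at 8 mpf. mt-co2, a subunit of cytochrome oxidase, was 1.73-fold higher at 8 mpf (1.68 to 1.78), at 9961 CPM against 5767. Lysosome and cathepsin genes had a centred median of 0.50 (percentile 99.5), with 2 of 14 members at least 2-fold higher, and of 0.22 after thinning. The protease gene ctsba was 2.32-fold higher (2.16 to 2.49) and ctsd 1.504-fold higher. Cytosolic ribosomal proteins had a centred median of 0.57 (percentile 97.9), with all 56 members within 2-fold, such as rps12 at 1.47-fold and rps29 at a ratio of 0.967. Lipid and cholesterol genes had a centred median of 0.51 (percentile 96.4), with 8 of 9 members within 2-fold and 1 at least 2-fold lower. Growth factor receptors had a centred median of 0.33 (percentile 98.7) and of 0.93 after thinning, although more members were at least 2-fold lower at 8 mpf (5 of 22) than at least 2-fold higher (1), with 16 between. fzd7a, a Wnt receptor gene, was 3.33-fold lower and erbb2 4.12-fold lower, while fgfr3 was 1.47-fold higher (1.06 to 2.03). Thyroid hormone response genes had a centred median of 0.48 (percentile 97.2) over 5 members, 1 of them at least 2-fold lower, and this was −0.24 in barcodes of at least 5000 UMIs.

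Thyroid transcription factors had a centred median of −0.29 (percentile 10.6) over 5 measured members, which turned to 0.43 when the CPM of each cell was averaged. Thyroid hormone synthesis genes had a centred median of 0.05 (percentile 29.4) over 9 members, and −0.08 after thinning. Nuclear oxidative phosphorylation genes had 0.21 (percentile 91.8) over 37 members, and −0.07 with averaging over cells. Junction and cytoskeleton genes had −0.20 (percentile 1.47), with krt4, a keratin gene, 2.70-fold lower. Inflammatory and acute phase genes had −0.42 (percentile 2.56), with 4 of 11 members at least 2-fold lower and 2 at least 2-fold higher, and −0.06 when members with at least 5 UMIs were counted. The chemokine genes ccl19a.1 and ccl25b went opposite ways, 14.8-fold lower (4.92 to 73.0) and 2.36-fold higher. Interferon response genes had 0.01 (percentile 58.4) over 11 members and antigen presentation genes 0.06 (percentile 42.1) over 9. Haemoglobins, striated muscle genes and neuropeptides had 0 measured members, and other red blood cell genes had 1, so these lists were not measured.

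The third comparison looked at the other cell classes at 8 mpf against 2 mpf. In macrophage-like cells grn2, a granulin gene among the markers of the class, was 591 CPM at 8 mpf and 14.4 CPM at 2 mpf, 41.1-fold higher (28.2 to 62.6), and the coagulation factor XIII gene f13a1a.1 was 33.0-fold lower (23.3 to 48.0). In endothelial-like cells vwf, which encodes von Willebrand factor, was 7.68-fold higher (5.54 to 10.7), and the myostatin gene mstnb had 75 and 0 UMIs, at least 5.25-fold lower. In epithelial-like cells calb2a, a calcium-binding protein gene, had 92 and 0 UMIs, at least 41.8-fold lower. In fibroblast-like cells saa, the acute phase gene serum amyloid A, was 14.9-fold higher (9.96 to 23.0). The type I collagen gene col1a2 was lower in 8 of 8 classes, by 2.60-fold to 19.8-fold, and extracellular matrix genes were below all random lists in each class.

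The remaining genes named in T-cell-like cells were si:dkey-203a12.2 and si:dkey-203a12.7, at least 59.8-fold and 34.3-fold higher at 8 mpf, si:dkey-203a12.6 with 1 and 275 UMIs (154-fold, 27.3 to 6090), CABZ01058646.1 (at least 18.1-fold) and si:dkey-77g12.1 (at least 16.2-fold). Lower were si:dkey-78l4.1 (119-fold, 79.2 to 189), si:dkey-78l4.2 (119-fold, 72.8 to 208), BX511246.1 (41.2-fold), si:ch211-277c7.6 (15.7-fold) and BX323596.2 (11.8-fold). The si:dkey-203a12 and si:dkey-78l4 symbols are series of near neighbours by name, and reads shared between them were not analysed here. In macrophage-like cells BX908782.3 (46.3-fold), prokr1a (39.5-fold), BX005223.1 (at least 26.9-fold) and CXCL11 (1 of many) (at least 16.9-fold) were also higher. BX511246.1 with 201 and 1 UMIs (64.2 to 14350), the chemokine gene ccl39.1 (93.8-fold, 45.1 to 235), si:ch211-283g2.3 (at least 42.0-fold) and ms4a17a.9 (34.6-fold) were lower.

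In epithelial-like cells si:busm1-104n07.3 and si:ch211-134a4.2, both at 0 UMIs at 2 mpf, were at least 67.2-fold and 65.7-fold higher, with si:dkey-18p12.4 (65.6-fold), si:dkey-32e6.6 (52.1-fold) and CFAP70 (at least 17.6-fold). Lower there were BX511246.1 (169-fold, 29.8 to 6733), apnl (52.5-fold, 23.8 to 145), si:dkey-224b4.5 (at least 36.4-fold) and si:ch211-287c22.1 (at least 28.2-fold). The epithelial-like class took different shares of its cells from its 4 clusters, which held 254, 166, 101 and 28 cells at 2 mpf and 190, 398, 193 and 110 at 8 mpf. In fibroblast-like cells HSPA8 (1 of many) was 46.4-fold higher, coch, the gene of the matrix protein cochlin, 38.1-fold, ALKBH3 (1 of many) 17.0-fold and zgc:152791 14.98-fold. si:dkey-11f4.20 had 1165 and 0 UMIs, at least 135.7-fold lower, BX908782.1 was 199-fold lower (85.0 to 612), a second gene row annotated to PTGFRN at least 73.9-fold and si:dkey-29l4.4 at least 20.7-fold. The other of the 5 lowest there, a gene with a clone-based symbol, had 261 and 3 UMIs, 30.4-fold lower (10.3 to 148).

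In endothelial-like cells zgc:152791 (15.1-fold), wu:fj16a03 (7.78-fold), eif4ebp3l (4.99-fold), of a family of translation repressors, and the glutamine synthetase gene glula (4.201-fold) were higher. Lower were ms4a17a.11 (7.77-fold), serpinh1b (7.51-fold), a collagen chaperone, dnajb1b (3.77-fold), a heat shock co-chaperone, and the aquaporin gene aqp1a.1 (at least 3.92-fold). In lymphatic endothelial-like cells si:zfos-464b6.2 (7.83-fold), fibinb (7.52-fold), the lysyl oxidase-like gene loxl2a (5.07-fold), zgc:152791 (4.88-fold) and eif4ebp3l (4.09-fold) were higher. si:dkey-27i16.2 (11.07-fold), ms4a17a.9 (10.1-fold), the transcription factor gene sox11a (8.41-fold), the linker histone gene h1f0 (7.71-fold) and si:dkey-203a12.9 (6.88-fold) were lower. In proliferating cells hp.1 (30.8-fold), grn2 (at least 30.6-fold), si:dkey-119g10.4 (156-fold, 27.7 to 6189) and zgc:158701 (81.8-fold, 14.4 to 3262) were higher. Lower there were tagln (at least 63.9-fold), actc1b (at least 51.8-fold), ttn.2 (at least 29.4-fold) and agr2 (127-fold, 34.7 to 1056). rho, at least 59.2-fold higher, and mylpfa, at least 104.5-fold lower, each came from 1 barcode of that class. Genes known from macrophages, muscle, mural and epithelial cells are thus among those named in this class, and its striated muscle genes had a centred median of −5.45 over 5 members and extracellular matrix genes −2.93.

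AP-1 and immediate early genes were also low at 8 mpf in fibroblast-like cells, with a centred median of −0.63 (percentile 0.0100), and in macrophage-like cells, with −0.36 (percentile 0.0400). Their percentiles were 13.9 in T-cell-like, 27.0 in epithelial-like, 41.9 in endothelial-like, 66.6 in proliferating and 85.3 in lymphatic endothelial-like cells. Heat shock genes lay at percentile 0.135 in endothelial-like, 0.1 in epithelial-like and 0.0400 in proliferating cells, and at 81.6 in lymphatic endothelial-like cells. The fibroblast-like comparison sets different clusters against each other, and within the 1 cluster with 719 and 758 cells extracellular matrix genes had a centred median of −1.26, against −0.93 in the class. AP-1 and immediate early genes had −0.27 in that cluster (percentile 7.25), and −0.33 when the unnamed agrp2 clusters were counted with the class.

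The fourth comparison set thyrocyte-like cells against every other named class of at least 50 cells within each library, so cells of unnamed clusters were left out. pax8 was 296 CPM in thyrocyte-like cells at 2 mpf against 6.90 in the next highest class, and 131 against 1.54 at 8 mpf. nkx2.4b was 341 against 5.61 CPM at 2 mpf and 287 against 8.53 at 8 mpf. met, the receptor of hepatocyte growth factor, was 162 CPM (145 to 181) against 14.03 at 2 mpf and 164.5 CPM (139 to 193) against 7.77 at 8 mpf. vegfaa was also highest in thyrocyte-like cells, at 258 CPM (236 to 282) against 186 (169 to 204) in epithelial-like cells at 2 mpf, and 158 (133 to 186) against 92.9 (82.9 to 104) at 8 mpf.

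Of the thyroid transcription factors measured in both libraries, 3 of 4 were higher in thyrocyte-like cells than in every such class at both ages, pax2a among them, at 259 CPM against 25.3 in proliferating cells and 134 against 1.18 in macrophage-like cells. Of the hormone synthesis genes that were not markers, 3 of 5 were: DUOXA2, a maturation factor of the oxidase that makes hydrogen peroxide (94.1 and 80.01 CPM), the thioredoxin reductase gene txnrd1 (355 and 430 CPM) and dio1. dio1 was 111 CPM (97.1 to 127) against 58.1 (43.9 to 75.5) in mural-like cells at 2 mpf, and 386 against 93.9 in endothelial-like cells at 8 mpf. Among ligands 1 of 21, and among receptors 2 of 22, fgfr3 and met, were higher in both libraries, and of the neuropeptides 0 were measured. For each of these genes, the interval of at least 1 class of under 50 cells reached that of thyrocyte-like cells in 1 or both libraries. With 0 UMIs of a gene, the endothelial-like class at 8 mpf still had an upper bound of 31.5 CPM. Genes with a lower bound under this in thyrocyte-like cells could not be called higher. Those included foxe1, duox and lrp2a, with lower bounds of 9.33, 29.0 and 18.0 CPM at 8 mpf, so the counts above are limited by depth.

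The fifth comparison looked at variation between single thyrocyte-like cells, after thinning to 1100 UMIs, which 262 cells at 2 mpf and 117 at 8 mpf reached and 59 and 46 did not. IYD was detected in 48.5% (42.3 to 54.7) of the thinned cells at 2 mpf and 11.97% (6.70 to 19.3) at 8 mpf, against 69.8% and 37.4% before thinning. pax2a was detected in 24.8% (19.7 to 30.5) and 17.1% (10.8 to 25.2), with overlapping intervals, against 60.4% and 41.1% before thinning. crhbp was detected in 4.96% and 32.5% of the thinned cells, and dio1 in 11.07% and 29.9%. Before thinning these were 8.10% and 44.8% for crhbp, and 33.6% and 51.5% for dio1. In thinned macrophage-like cells, which should lack IYD and pax2a, 0 of 261 cells at 2 mpf and 0 of 445 at 8 mpf had a UMI of either gene, which allows, at a limit of 3 counts, up to 1.15% and 0.674% of cells with a UMI. Before thinning 0.533% and 0.202% of them had a pax2a UMI, and 0.8% and 0.605% an IYD UMI. Their median depths were 2272 and 6181 UMIs, against 5909 and 2106 in thyrocyte-like cells, and 114 and 51 of them fell short of the thinned depth. In those macrophage-like cells crhbp was found in 0.766% and 0.449%, and dio1 in 1.15% and 0.225%.

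The largest variance-to-mean ratios among thinned thyrocyte-like cells were those of malat1 (50.002 at 2 mpf and 54.9 at 8 mpf), tg (49.9 and 85.3) and zgc:158463 (12.5 and 62.1). Next came the heat shock genes hsp70l (12.1 and 11.3) and hsp90aa1.2 (9.67 and 11.7), then the retinol-binding protein gene rbp4 (8.61 and 8.08). hspb1, si:dkey-153m14.1, hsp70.3 and cxcl12a completed the first 10. pax2a had 1.16 and 1.75, pax8 1.24 and 1.005, and IYD 1.21 and 0.846, where counts from cells of equal expression give about 1. Across cells, the summed AP-1 and immediate early UMIs went with hsp70l, with a Spearman rho of 0.600 at 2 mpf and 0.686 at 8 mpf. With pax2a rho was −0.116 and −0.0814, at percentiles 7.99 and 22.4 of genes of like abundance, and −0.00403 at 2 mpf when cells were thinned to 50% of that depth. Over 20 random thinnings to 1100 UMIs it ran from −0.192 to −0.00530 at 2 mpf and from −0.249 to 0.0619 at 8 mpf, so its sign at 8 mpf turned between draws. Cells of 1 library are not independent replicates, so no test was made of these correlations.

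Thyrocyte-like barcodes differed in content with their depth, on a division at 5000 UMIs chosen after seeing the data. Barcodes under 5000 UMIs numbered 150 at 2 mpf and 95 at 8 mpf, with median depths of 1208 and 1114 UMIs, and those above numbered 171 and 68, with 9355 and 10634. tg was 88689 CPM in the shallower and 24151 CPM in the deeper barcodes at 2 mpf, and 79455 and 17611 CPM at 8 mpf. pax2a was 356.3 and 246 CPM at 2 mpf, and 433 and 82.3 CPM at 8 mpf. Its log2 ratio of 8 mpf over 2 mpf was −1.58 in the deeper and 0.28 in the shallower barcodes. In the shallower barcodes the ratio was 1.21 (0.852 to 1.72), an interval that includes 1. Mitochondrially encoded genes gave 6.27% of UMIs in the shallower and 1.21% in the deeper barcodes at 2 mpf, and 9.92% and 1.46% at 8 mpf.

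**Figure D3:**
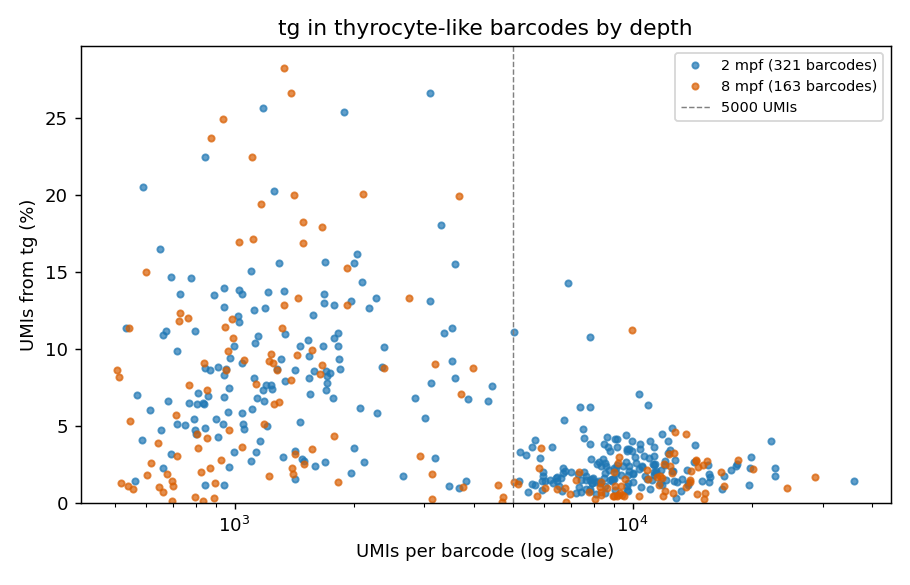
Share of UMIs from tg, in percent, against UMIs per barcode on a log axis, for 321 thyrocyte-like barcodes at 2 mpf and 163 at 8 mpf, 1 point per barcode, with a dashed line at 5000 UMIs. Shallower barcodes tend to carry a larger share of tg, with 88689 CPM against 24151 at 2 mpf and 79455 against 17611 at 8 mpf.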

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

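The result in this part was noticed after the data were seen, and no test was made of it. In the 2 mpf library, 44 barcodes had more than 50% of their UMIs from si:dkey-153m14.1, against 0 barcodes in the 8 mpf library. They stood out because they carry a signal in barcodes that the filters removed and no comparison used. Their median depth was 3177.5 UMIs, within a range of 696 to 27697, and the median share from this gene was 95.7%. Of these barcodes, 0 passed the filters, so none enters the values above. No technical or biological explanation was tested.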

How the results depend on the processing

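The splits of thyrocyte-like barcodes at 5000 UMIs and the regroupings of fibroblast clusters were chosen after seeing the data; the other alternatives were fixed in advance. No paired analysis was possible because each age had 1 library. Over all alternatives, 93 of the recomputed main values stayed within their main interval, 16 moved beyond it and 3 turned sign. For the other recomputed values these numbers were 403, 78 and 5. Those values include single genes, lists, shares of other classes and the correlation of pax2a with AP-1 genes. Some alternatives could not move some values, which count among those that stayed. A higher minimum of UMIs per gene leaves each gene's ratio as it was. Changes of scaling leave each list's median relative to all genes as it was. Expression in other classes was recomputed only for the fibroblast regroupings, while shares of several other classes were recomputed too. In every alternative that gave a value, IYD stayed lower (log2 −2.33 to −1.99), pax8 lower (−1.38 to −0.75) and dio1 higher (1.44 to 1.88, with no value in barcodes under 5000 UMIs), and the AP-1 list stayed below the median of all genes (−0.46 to −0.07). For the values that follow the cause was not tested, and log2 values are of 8 mpf over 2 mpf in thyrocyte-like cells. A higher minimum of UMIs per cell gave a thyrocyte-like share of 6.04% at 2 mpf and tg −0.27. A limit of 10% mt- UMIs gave a share of 2.27% at 8 mpf, tg −0.53 and ribosomal proteins, centred, 0.65. Scaling without the 20 most abundant genes gave tg −0.21, and median of ratios −0.17. Averaging the CPM of each cell gave tg −0.0011, pax2a 0.18, nkx2.4b 0.15, ribosomal proteins 0.41 and nuclear oxidative phosphorylation −0.068. Thinning every cell to the same depth gave tg 0.070, pax2a −0.38, nkx2.4b 0.20 and ribosomal proteins 0.49. A minimum of 5 UMIs per member gave ribosomal proteins 0.53. Barcodes of at least 5000 UMIs gave tg −0.46 and pax2a −1.58. Those under 5000 gave tg −0.16, pax2a 0.28, pax8 −0.75, nkx2.4b 0.44 and nuclear oxidative phosphorylation −0.17. There the intervals of the ratio included 1 for pax2a (0.852 to 1.72) and nkx2.4b (0.950 to 1.93). At 8 mpf, pax2a and nkx2.4b had 121 and 258 UMIs over 163 cells, against 118 for pax8 and 127 for IYD. Few UMIs alone thus do not set apart the genes whose sign turned.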

Other observations

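The tests of the fasting and glucocorticoid set, the collagens and the barcode depth were chosen only after the results were seen, as were the genes and classes singled out here, whereas the antigen presentation list and the ligand and receptor lists were fixed in advance. The list of antigen presentation genes lay high among random lists at 8 mpf in several classes, with most members within 2-fold. Its median log2 ratio, relative to all genes of the class, was 1.105 in endothelial-like, 0.93 in lymphatic endothelial-like, 0.79 in epithelial-like, 0.65 in T-cell-like and 0.53 in macrophage-like cells, each above 99% of random lists. By ratios not centred on all genes, members at least 2-fold higher at 8 mpf numbered 2 of 7, 3 of 8, 4 of 15, 1 of 13 and 1 of 15. These counts follow the order of classes above, and 1 epithelial-like member was at least 2-fold lower. The median was 0.59 in proliferating cells (percentile 94.6), 0.25 in fibroblast-like cells (percentile 83.5) and 0.06 in thyrocyte-like cells (percentile 42.1), and differences between classes were not tested. BX511246.1 had 238, 201, 124 and 92 UMIs at 2 mpf in thyrocyte-like, macrophage-like, epithelial-like and T-cell-like cells, and 2, 1, 1 and 4 at 8 mpf. lyz, the lysozyme gene, was higher at 8 mpf in 8 of 8 classes, by 7.87-fold to 22.2-fold, in a library where neutrophil-like cells were 2.48% of cells against 0.601%.

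Signalling genes were divided between classes. The chemokine gene cxcl12a was 6225 CPM in fibroblast-like cells at 2 mpf and 9038 CPM at 8 mpf, and 6322 and 4537 CPM in lymphatic endothelial-like cells. Its receptor gene cxcr4b was 1757 and 2901 CPM in neutrophil-like, 1090 and 1669 CPM in macrophage-like and 653 and 1043 CPM in T-cell-like cells. Among named classes of at least 50 cells, vegfaa was highest in thyrocyte-like cells at both ages. Its receptor gene kdrl was 1489 CPM at 2 mpf and 1314 CPM at 8 mpf in endothelial-like cells. A cluster of 28 cells with tph1a, grp and scg3 was seen only at 8 mpf, and an unnamed cluster of 43 cells with epcam and krt5 only at 2 mpf.

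The median of a set of 21 genes known from fasting and glucocorticoid responses lay above all random lists at 8 mpf in 8 of 8 classes, and the set was chosen because some of its members had stood out. In thyrocyte-like cells 9 members were at least 2-fold higher, 3 at least 2-fold lower and 9 between, while 11 of 17 members in T-cell-like, 10 of 18 in macrophage-like and 9 of 16 in lymphatic endothelial-like cells were within 2-fold. pdk2b, a kinase that holds back pyruvate oxidation, was higher in 8 of 8 classes (2.47-fold to 4.71-fold), and fkbp5, a glucocorticoid target, in 7 of 8 (1.69-fold to 3.13-fold), with a ratio of 1.22 (0.917 to 1.63) in T-cell-like cells. klf9, a glucocorticoid target too, was higher in 5 of 8 classes, and sesn1 in 6 of 8, with a ratio of 0.926 in lymphatic endothelial-like cells. The set overlaps lists fixed in advance: klf9 is also in the thyroid hormone response list, and cebpd in the AP-1 and immediate early list. Which response klf9 reflects was not tested.

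For 14 genes of this set, the lowest class at 8 mpf held a median of 10.0% of the highest. For the source genes tg, lyz, c1qb and cdh5 this was at most 0.187%, although 21.9% if neutrophil-like cells are not counted as the source of lyz. The median argues against free RNA shared by all droplets for these genes as a group, but not for each gene and class. cebpd held 0.716%, and pdk2b and tsc22d3 were lowest in thyrocyte-like cells, at 4.59% and 4.81%. At 8 mpf tg was 1092 CPM in endothelial-like cells, against 26823 in thyrocyte-like cells, well above its lowest class. The set's smallest median relative to all genes was 0.76. Because the set was chosen for members that stood out, that value cannot decide on scaling by total UMIs. A shared fasting-like state of the 8 mpf fish cannot be told from others, with a median of −0.22 for ribosome biogenesis and 0.07 for autophagy over classes, each in that direction in 6 of 8 classes, and with 0.25 and −0.05 in thyrocyte-like cells. The hour at dissection stays open as well, with circadian clock genes at 0.59 from all genes in the class farthest from them and 0.08 in thyrocyte-like cells, and age, fish and library cannot be told apart with 1 library per age.

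Type I collagen genes were lower at 8 mpf in 8 of 8 classes, col1a1a by 2.53-fold to 27.5-fold. In classes that should not make them, free RNA from fibroblast-like cells is a candidate source: at 2 mpf the ratios between these genes in macrophage-like cells lay within 0.34 on the log2 scale of those in fibroblast-like cells. Their col1a2 stood at 3.28% of the fibroblast-like level at 2 mpf and 0.951% at 8 mpf. For fibroblast-like cells themselves, different clusters at each age are argued against as the whole cause, since 11 collagens had a median of −1.45 relative to all genes within 1 cluster present at both ages, against −1.10 in the class. Age stays open and untested.

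tg took 3.67-fold and 4.51-fold more of the UMIs in thyrocyte-like barcodes of under 5000 UMIs than in deeper ones, at 2 mpf and 8 mpf. Free thyrocyte RNA in barcodes of other content would raise all thyrocyte genes alike, but the median of 7 others was 0.364 and 0.384 of the factor of tg, although pax2a at 8 mpf reached 1.17. Damaged cells that lost cytosol may contribute: ribosomal protein genes were at most 0.416 of their share in the deeper barcodes, while mitochondrially encoded genes were 5.18-fold and 6.79-fold higher. malat1, a nuclear RNA, was 3.35-fold and 3.95-fold higher. A true state of small thyrocytes was not tested and stays open.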
